A study of Homo sapiens with 12 samples.

How the data were processed

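RNA was measured in 12 cultures of the hepatocellular carcinoma lines Hep3B and Huh1, 3 for each line and siRNA (RDBP or scrambled control), 48 h after transfection. Per the labels, cells were plated on dishes in sets of 4, total RNA was extracted with Trizol, and about 100 ng was reverse transcribed into biotin-labelled cDNA for Affymetrix arrays. Per the series design text, the authors removed outlier arrays by Spearman or Pearson correlation until 3 per group were left. The deposited values are log2 expression levels per probe set, which the authors computed with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, quantile normalizes arrays and summarizes the probes of a probe set. The values ran from 0.89 to 14.48, above the 11.09 that the natural log of a 16-bit scanner's highest value allows, which fits log2. The array version, its annotation, the genome build, the software versions and whether all groups were normalized together are not given in the sources used here.

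The table held 70523 probe sets, 67528 of them transcript clusters and 2995 controls or others. In the annotation used, 23781 transcript clusters list exactly 1 gene symbol, 1543 several and 42204 none. Genes tested were the clusters with exactly 1 symbol, and for the 479 genes with more than 1 cluster the one with the highest mean over all arrays, which gave 22465 genes with a median log2 level of 4.83. No filter on dim genes was used. The probe set of NELFE lists several symbols, so it was fitted as an extra gene in the same model and left out of the counts and the lists. Median log2 values per array were 3.642, 3.662 and 3.675 for Hep3B control siRNA, 3.665, 3.647 and 3.659 for Hep3B RDBP siRNA, 3.724, 3.692 and 3.647 for Huh1 control siRNA, and 3.760, 3.689 and 3.683 for Huh1 RDBP siRNA. Background probe sets had medians from 2.37 to 2.75, and their level rises with GC content, so they set no single detection limit. After seeing the data, named genes were marked in the text as low where their group mean lay below the median of all probe sets. Correlations within groups ran from 0.9915 to 0.9967 and between lines from 0.9665 to 0.9753, and 0 pairs of arrays held identical values.

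Before the data were examined the groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed. One linear model with a mean for each of the 4 groups and no covariate was fitted to all 12 arrays with limma 3.58.1 (R 4.3.3; lmFit and eBayes, 8 residual and 2.29 prior degrees of freedom). Its contrasts were RDBP siRNA minus control siRNA in Hep3B and in Huh1, the Huh1 response minus the Hep3B response (interaction), and Huh1 control minus Hep3B control. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. For limma ± values are SE, and a called gene changed by 2-fold when its absolute log2 fold change was also at least 1. The overlap of the lines was compared with the number expected for independent lists by Fisher's exact test.

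Of 41 gene lists written down from textbook knowledge 38 had at least 5 measured members. These were tested against all other genes with camera of limma at its preset correlation between genes of 0.01, with adjustment over the lists tested, and again with the correlation estimated for each list. Beside each list stand the members called over all genes and those called when adjusted over the list alone. A random list matched on brightness was drawn 10000 times per list from 50 brightness bins.

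Named genes are NELFE and MYC, the 8 called genes with the largest increase and the 8 with the largest decrease per line, the 5 largest differences each way between responses and between lines, and 2 to 4 members of each described list with the smallest adjusted p. The largest changes were limited to symbols that look protein-coding and to genes with all 3 knockdown arrays beyond all 3 control arrays. Genes that fall outside this rule are marked where they are named.

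The scripts were tested on simulated data made for 22465 genes, of which 100 were changed by 0.5 and 100 by 1 in each line. With the same spread in all arrays, 80% of genes changed by 0.5 and 96% of those changed by 1 on the log2 scale were called in the Hep3B comparison, with 2.22% of calls false. In the Huh1 comparison the shares were 79% and 95% with 8.42% false, and in the interaction 60.1% and 90% with 2.91% false. With each gene's observed spread in a line taken as its true spread, 78% and 96% were called in Hep3B with 4.92% false. The shares were 82% and 96% in Huh1 with 28.5% false, and 61.6% and 91% in the interaction with 7.29% false. When the arrays of the line alone were fitted, 57% and 86% were called in Huh1 with 5.3% false. Among 20 simulated lists of 40 members, the one shifted by −0.2 was called in each line and 0 others were. The simulated noise was independent between genes, so this check could not show false list calls that arise from correlated genes.

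The alternatives fixed beforehand were quantile normalization of all arrays again or within each line, median centring, dim genes left out, the mean of all probe sets of a gene, every transcript cluster tested on its own, a variance trend, robust variance, array weights, the replicate number as a block, each array left out in turn, the arrays of 1 line alone, an adjusted p under 0.01, and for lists the estimated correlation, fry and ranks. A further 3 were chosen after seeing the data: cyclic loess between arrays, both Huh1 arrays numbered 1 left out, and 444 probe sets added whose several symbols name a single gene. Splits of the 6 arrays of a line into 3 against 3 number 10, and those of both lines together 100. Raw scanner files were not used here. Transcript clusters without a single gene name were counted but not named.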

Results

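Transcript levels were measured on Affymetrix arrays in 12 cultures of 2 hepatocellular carcinoma cell lines, Hep3B and Huh1, 48 h after transfection with an siRNA against RDBP or with a scrambled control siRNA. RDBP is an older symbol of NELFE, a subunit of the negative elongation factor (NELF) complex that holds RNA polymerase II paused just downstream of the transcription start and that binds RNA through an RNA recognition motif. Each of the 4 groups held 3 arrays. Plates had been set up in sets of 4, and the authors removed arrays that correlated poorly with the others until 3 were left in each group, which narrows the spread within groups. The replicates were plates of a single line, so p-values measure the spread between plates. Hep3B cells grew in minimum essential medium and Huh1 cells in Dulbecco's modified Eagle medium, each with 10% fetal bovine serum, so line and medium cannot be told apart. Median log2 values over all probe sets ran from 3.64 to 3.76 per array, and the mean correlation of an array with the others of its group from 0.9918 to 0.9964. Huh1 RDBP siRNA replicate 1 had the lowest correlation, the highest median and the highest median over background probe sets (2.75). Precision is limited by the 3 arrays per group. In every gene picked by the naming rule and given below as risen or fallen after RDBP siRNA, 3 of 3 knockdown arrays lay beyond all 3 control arrays. Chance gives this for 10% of unchanged genes, but the rule required it of the largest changes. List members were picked for small adjusted p, so the separation is no independent support for either.

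The siRNA lowered its target in both lines. NELFE averaged a log2 level of 5.58 ± 0.07 (SD, n = 3) in Hep3B cells with control siRNA and 4.85 ± 0.10 (n = 3) with RDBP siRNA, which left 60.4% of its signal. In Huh1 cells it went from 5.83 ± 0.05 to 4.99 ± 0.03 (SD, n = 3 each), which left 56.0%. The log2 fold changes were −0.73 (95% confidence interval −0.85 to −0.60; limma adjusted p = 1.73e-05) and −0.84 (−0.96 to −0.71; adjusted p = 6.22e-05), with 3 of 3 arrays lower in each line. Exact permutation gave p = 0.1 in each line, the smallest two-sided value that 3 arrays against 3 allow. The knockdown did not differ detectably between lines (difference −0.11 ± 0.08 SE, adjusted p = 0.698), and every array lay on the side its label names. Because the probe set of NELFE lists several symbols, it was fitted in the same model and not counted among the genes tested.

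**Figure D1:**
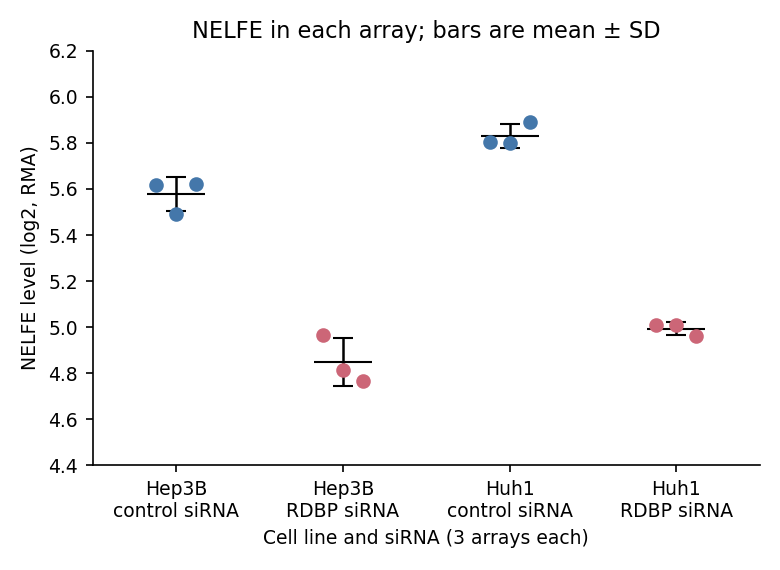
NELFE level (log2, y axis) in each of the 12 arrays by cell line and siRNA (x axis); points are arrays, horizontal marks are group means and error bars are SD over 3 arrays. All RDBP siRNA arrays lie between 4.77 and 5.01, below all control arrays of either line, the lowest of which is at 5.49.

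The series title ties RNA-binding proteins to MYC signaling in hepatocellular carcinoma, so MYC itself was examined next. MYC, the transcription factor that drives growth and ribosome production, did not pass the test in either line. Its log2 fold change was 0.03 ± 0.05 (SE, adjusted p = 0.901) in Hep3B and −0.18 ± 0.05 (adjusted p = 0.0892) in Huh1, and the responses did not differ detectably (−0.21 ± 0.07, adjusted p = 0.212). Without Hep3B control siRNA replicate 2 the Huh1 change was called (adjusted p = 0.0357), and the small Hep3B value was −0.03 there and −0.001 without Hep3B RDBP siRNA replicate 1. Of the 13 measured members of the MYC network (MYC, MAX and their partners), 1 rose and 4 fell in Hep3B, and 0 rose and 3 fell in Huh1 by limma. Adjusted over the list alone the counts were 1 and 5 in Hep3B and 0 and 4 in Huh1. As a list they did not stand apart from other genes in Hep3B (camera adjusted p = 0.43, with a median of 0.0286 although camera pointed down) or in Huh1 (0.0564).

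In Hep3B cells with RDBP siRNA, lists of liver plasma proteins and of the amino acid response fell. TM4SF1, a tetraspanin-like surface protein, rose 6.62-fold (log2 2.73 ± 0.12 SE, limma adjusted p = 7.75e-07). DCBLD2, a transmembrane receptor, rose 4.97-fold (2.31 ± 0.07, adjusted p = 1.11e-07), and NES, which encodes the intermediate filament nestin, 4.31-fold. CPB2, a carboxypeptidase of plasma that restrains clot lysis, fell by 2.41 on the log2 scale, to a level 5.33-fold lower (adjusted p = 8.78e-06). CHAC1, which degrades glutathione and is a target of ATF4, was much lower (log2 −2.00 ± 0.06, adjusted p = 1.11e-07), and RPS19, a protein of the small ribosomal subunit, 3.94-fold lower.

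Among the other large increases in Hep3B were B3GALT1, a galactosyltransferase (3.75-fold), HAS2, which makes hyaluronan (3.75-fold), MICAL2, an oxidase that disassembles actin filaments (3.64-fold), the chemokine receptor CXCR4 (log2 1.77) and PGM2L1, which makes glucose bisphosphate (3.38-fold), all with adjusted p of 6.04e-06 or lower. The other large decreases were RAB8B, a GTPase of membrane traffic (3.03-fold lower), APOB, the backbone of liver lipoproteins (2.97-fold lower, adjusted p = 0.00153), PDZK1, a scaffold of membrane transporters (2.93-fold lower), and EIF4EBP2, a repressor of cap-dependent translation (2.90-fold lower). PDZK1P1, a pseudogene of PDZK1, was 2.89-fold lower, and its signal cannot be separated from that of its near-identical parent. Of 22465 genes tested, 2925 changed at an adjusted p under 0.05, 1455 higher and 1470 lower, which is 13% of the genes. Most changes were small, with a median absolute log2 fold change of 0.37 among the genes called, and 138 genes changed at least 2-fold (70 higher, 68 lower).

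Secreted liver proteins moved in a single direction in Hep3B. Of 37 measured genes for proteins that hepatocytes secrete into plasma, 21 fell and 0 rose, or 23 and 0 adjusted over the list alone (median log2 fold change −0.33, camera adjusted p = 4.15e-16). ORM1 and ORM2, near-identical genes for the acute-phase protein orosomucoid, fell by 1.37 and 1.43 on the log2 scale, FGB, the fibrinogen beta chain, by 1.08, and KNG1, the precursor of kinins, by 0.94. The fall of KNG1 is a lower bound at most, since its mean with RDBP siRNA (3.35) lay below the median of all probe sets (3.66). Among 35 complement and coagulation genes 13 fell and 0 rose (16 and 0 adjusted over the list alone; camera adjusted p = 9.33e-09). Besides CPB2 they included SERPINF2, the inhibitor of plasmin (−0.97), C3, the central complement protein (−0.78), and F7, a clotting factor (−0.84). Both lists stayed past the threshold with an estimated correlation between genes (adjusted p = 0.0231 for each). For liver transcription factors, with 5 of 20 lower and 2 higher (6 and 2 adjusted over the list alone), the list as a whole did not pass (camera adjusted p = 0.0883).

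Genes of the ATF4 and amino acid response fell in Hep3B. Of 39 measured members 25 fell and 2 rose, or 26 and 2 adjusted over the list alone (median −0.28, camera adjusted p = 1.25e-17; 0.0286 with an estimated correlation). After CHAC1 the smallest adjusted p-values belonged to MTHFD2 (−0.95) and SHMT2 (−1.09), enzymes of mitochondrial one-carbon metabolism, and to PSPH (−0.95), the last enzyme of serine synthesis. MTHFD2 and PSPH each had the same value in all Hep3B RDBP siRNA arrays (7.404 and 7.973). Their spread may thus be understated and their adjusted p too small. Ribosomal protein genes fell as well, with 22 of 46 measured members lower and 0 higher (31 and 1 adjusted over the list alone; median −0.19, camera adjusted p = 1.02e-15). With an estimated correlation this list had an adjusted p = 0.0558. RPS15A and RPLP1 fell by 1.18 and 1.16 on the log2 scale, while the decrease of RPL30 was small (−0.31 ± 0.04 SE).

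Immediate early genes, which respond to growth factors and stress within minutes, moved the other way. Of 37 measured members 18 rose and 1 fell in Hep3B, or 19 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 9.25e-09; adjusted p = 0.121 with an estimated correlation). They included KLF6 (1.42), the zinc finger factor EGR1 (0.90), the nuclear receptor NR4A2 (0.42) and SPRY4 (0.96), a feedback inhibitor of receptor tyrosine kinase signaling. Targets of the coactivator YAP and its TEAD partners also rose, 10 of 27 higher and 3 lower (12 and 3 adjusted over the list alone; median 0.14, camera adjusted p = 0.00214; adjusted p = 0.218 with an estimated correlation). MYOF (1.18), AMOTL1 (0.89), YAP1 itself (0.55) and the kinase LATS2 (0.44) had the smallest adjusted p-values. LATS2 had the same value (5.994) in all Hep3B control arrays, so its adjusted p may be too small. Outside the naming rule, the YAP target CCN2 had a lower log2 level with RDBP siRNA (8.632 to 8.936 against 9.308 to 9.352 in control arrays). ANKRD1, also outside the rule, had a higher one (9.641 to 9.99 against 9.095 to 9.117). In the list of TGF-beta, EMT and matrix genes 11 of 43 rose and 5 fell (11 and 6 adjusted over the list alone), among them VIM, encoding vimentin (1.06), CDH2, encoding N-cadherin (0.91), THBS1 (0.47) and TIMP1 (0.46). That list barely passed (camera adjusted p = 0.0446; adjusted p = 0.121 with an estimated correlation; percentile 96.2 of random lists matched on brightness) and did not pass without Hep3B control siRNA replicate 1 (0.0748) or Hep3B RDBP siRNA replicate 3 (0.0751).

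Cholesterol genes fell in Hep3B, 10 of 22 lower and 0 higher (12 and 0 adjusted over the list alone; median −0.22, camera adjusted p = 1.52e-06; adjusted p = 0.172 with an estimated correlation). MSMO1 (−0.64) and DHCR7 (−0.47) encode enzymes of sterol synthesis, SREBF2 (−0.31) its transcriptional activator and NPC1L1 (−0.26) a sterol transporter. Of 28 NRF2 and glutathione genes 7 were lower and 2 higher, the same counts adjusted over the list alone. The list had a camera adjusted p = 0.00271, or 0.24 with an estimated correlation. Lower members included GSR, glutathione reductase (−1.19), FTL, the ferritin light chain (−0.45), and HMOX1, which degrades heme (−0.39). NQO1, a quinone reductase named outside the rule, had a higher log2 level with RDBP siRNA (5.083 to 5.348 against 4.741 to 4.87). Autophagy and lysosome genes (7 of 31 lower, 2 higher, or 10 and 4 adjusted over the list alone; camera adjusted p = 0.0116; adjusted p = 0.44 with an estimated correlation) included the autophagy receptor SQSTM1 (−0.54) and the sialidase NEU1 (−0.63). With dim genes left out the autophagy list was not called (0.0633).

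MYC targets moved in both directions in Hep3B. Of 159 measured targets 30 fell and 14 rose, or 36 and 17 adjusted over the list alone (median −0.05, camera adjusted p = 0.0119; adjusted p = 0.671 with an estimated correlation). PA2G4, a growth regulator (−0.88), IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis (−0.51), and MRPL9, a mitochondrial ribosomal protein (−0.59), fell, whereas ODC1, the first enzyme of polyamine synthesis and a classical MYC target, rose (0.66 ± 0.05 SE, adjusted p = 9.47e-06). The call of the MYC target list ended without Hep3B control siRNA replicate 2 (adjusted p = 0.0529). Oxidative phosphorylation genes were called with 8 of 43 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.0187; adjusted p = 0.423 with an estimated correlation), led by SDHC (−0.88) and NDUFA2 (−0.50) of respiratory complexes II and I, but its median lay at percentile 7.57 of random lists matched on brightness. Fatty acid genes were called with 7 of 38 lower and 1 higher, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0484; adjusted p = 0.389 with an estimated correlation). Without Hep3B control siRNA replicate 1 neither passed (0.0748 and 0.151), nor did the first without control siRNA replicate 2 (0.0529) or the second without RDBP siRNA replicate 3 (0.103) or Huh1 control siRNA replicate 2 (0.0503).

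In all, 13 lists passed in Hep3B, 3 upward and 10 downward (4 and 8 after cyclic loess), and several chosen for this knockdown did not. Pausing and elongation factors, the proteins that work beside NELF, had 4 of 37 higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.737), DNA replication genes 7 of 66 higher and 12 lower (8 and 17; 0.415) and mitosis genes 7 of 68 higher and 11 lower (8 and 15; 0.141). Among the neighbours of NELFE in the MHC class III region 1 of 13 fell, on either adjustment (camera adjusted p = 0.777). Interferon-stimulated genes, which siRNA duplexes can induce, had 0 of 53 higher and 3 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.22). Markers of fibroblasts, endothelial cells and leukocytes did not stand apart (camera adjusted p = 0.657, 0.944 and 0.777).

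In Huh1, fewer genes were called, and most of the changes of at least 2-fold were decreases. RAB8B was 3.12-fold lower (log2 −1.64 ± 0.10 SE, limma adjusted p = 3.95e-05). CA12, a carbonic anhydrase, and BAG2, a cochaperone of HSP70, were each 2.64-fold lower (adjusted p = 9.92e-05 and 7.48e-05), ARMC1, a mitochondrial distribution factor, 2.59-fold lower and EIF4EBP2 2.43-fold lower. TPM4, a tropomyosin that stabilizes actin filaments, rose 2.68-fold (1.42 ± 0.05, adjusted p = 5.88e-07), RAB27B, a GTPase of vesicle secretion, 2.59-fold (adjusted p = 0.000825), and EREG, an epidermal growth factor receptor ligand, 2.10-fold.

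The remaining large decreases in Huh1 were ZBTB41, a zinc finger protein (2.80-fold lower), GCH1, the first enzyme of tetrahydrobiopterin synthesis (2.26-fold lower), and ENTPD5, a nucleotidase of the endoplasmic reticulum (2.25-fold lower). The remaining large increases were NTN4, a netrin of basement membranes (2.08-fold), MICAL2 (1.92-fold), BICD2, a dynein adaptor (1.92-fold), the membrane protein EMP1 (1.87-fold) and HABP4, a hyaluronan- and RNA-binding protein (1.84-fold). Of 22465 genes 918 changed, 368 higher and 550 lower, and 19 changed at least 2-fold (4 higher, 15 lower). The direction was not stable, with 435 higher and 419 lower without Huh1 RDBP siRNA replicate 1 and 2010 and 2147 with array weights, a setting that called 4157 genes in Huh1 and 4317 in Hep3B. The fold of EMP1 is a lower bound at most, since its mean in Huh1 control arrays (3.62) lay below the median of all probe sets (3.69). When the spread was estimated from the Huh1 arrays alone 159 of these 918 genes were called, among them 14 of the 16 largest changes but neither ZBTB41 (adjusted p = 0.0584) nor EMP1 (0.0708). Without Huh1 control siRNA replicate 2 the count was 496.

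Growth-related lists fell together in Huh1, each by a small median. Of 159 MYC targets 11 fell and 0 rose, or 29 and 2 adjusted over the list alone (median log2 fold change −0.11, camera adjusted p = 2.6e-13; adjusted p = 0.191 with an estimated correlation). As in Hep3B, PA2G4 (−0.62), IMPDH2 (−0.56) and MRPL9 (−0.68) fell, followed by the splicing factor SF3A1 (−0.42). DNA replication genes had 10 of 66 lower and 0 higher (19 and 1 adjusted over the list alone; median −0.13, camera adjusted p = 5.36e-11; adjusted p = 0.259 with an estimated correlation), among them RFC5 (−0.61), a subunit of the clamp loader, and the helicase subunit MCM4 (−0.37). Mitosis genes had 9 of 68 lower and 0 higher (18 and 1 adjusted over the list alone; median −0.11, camera adjusted p = 5.91e-09; adjusted p = 0.359 with an estimated correlation), among them ESPL1, which encodes separase (−0.57), CDCA8 of the chromosomal passenger complex (−0.52) and CKAP5 (−0.53). Ribosome biogenesis genes had 5 of 66 lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 2.4e-08; adjusted p = 0.359 with an estimated correlation), led by DDX52 (−0.35) and NOB1 (−0.37). When the spread was estimated from the Huh1 arrays alone, the MYC targets and mitosis genes named here stayed called, whereas RFC5, MCM4, DDX52 and NOB1 did not. MYC targets share 20 members with ribosome biogenesis and 12 with DNA replication. Huh1 RDBP siRNA replicate 1, the array with the lowest correlation (0.9918), moved with these lists: without it the medians of the MYC target, replication and mitosis lists were −0.08, −0.08 and −0.05, with each still called.

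Other lists called in Huh1 overlapped with those of Hep3B. ATF4 and amino acid response genes fell, 8 of 39 lower and 0 higher (13 and 1 adjusted over the list alone; median −0.16, camera adjusted p = 5.91e-09; adjusted p = 0.152 with an estimated correlation), including MTHFD2 (−0.62), SHMT2 (−0.56), ASNS, asparagine synthetase (−0.32), and CHAC1 (−0.45). Of 46 ribosomal protein genes 2 fell, RPS19 (−1.09) and RPS15A (−0.73), and 0 rose, on either adjustment (camera adjusted p = 1.27e-05; adjusted p = 0.282 with an estimated correlation), and the list was not called after quantile normalization (0.0502), with its median at percentile 11.8 of random lists matched on brightness. Complement and coagulation genes had 4 of 35 lower and 0 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.00046; adjusted p = 0.106 with an estimated correlation), among them SERPINF2 (−0.35) and C4BPA, an inhibitor of complement (−0.35, low on the array with RDBP siRNA at 3.43 and so a lower bound at most), and were not called with dim genes left out (0.0797). Liver transcription factors had 2 of 20 lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.000523; adjusted p = 0.0766 with an estimated correlation), GATA4 (−0.39) and ONECUT1 (−0.73). In the TGF-beta, EMT and matrix list 5 of 43 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00241; adjusted p = 0.0766 with an estimated correlation; percentile 91.5 of matched random lists), led by THBS1 (0.84 ± 0.04 SE), a matrix glycoprotein, and by TIMP3 (0.30). Among immediate early genes 3 of 37 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00674; adjusted p = 0.366 with an estimated correlation), with IER5 (0.38) and IER3 (0.55) first, and without Huh1 control siRNA replicate 2 neither passed (adjusted p = 0.0508 and 0.0804). IER3 also failed without Huh1 control siRNA replicate 3 (0.0635), RDBP siRNA replicate 1 (0.0846) or RDBP siRNA replicate 2 (0.0731). When the spread was estimated from the Huh1 arrays alone, SERPINF2 (adjusted p = 0.0764), C4BPA (0.0523), ONECUT1 (0.0564), TIMP3 (0.122), IER5 (0.112) and IER3 (0.164) were not called, and 38 of 76 genes named by rule in Huh1 were.

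A further 11 lists in Huh1 passed with all arrays but not when 1 array was left out, in most cases Huh1 control siRNA replicate 3 or RDBP siRNA replicate 1. Without control siRNA replicate 3 the adjusted p of pausing and elongation factors went from 0.0104 to 0.213 and that of heat shock genes from 0.0139 to 0.225, although single members fell clearly, CCNK, the cyclin of CDK12 (−0.92), and STIP1, an HSP70-HSP90 cochaperone (−0.97). Without RDBP siRNA replicate 1 hepatocyte secreted proteins, 1 of 37 lower in Huh1 (1 adjusted over the list alone), went from 0.0251 to 0.236. With an estimated correlation these 3 lists had an adjusted p = 0.445, 0.366 and 0.366, and the medians of the first 2 lay at percentiles 37 and 41 of random lists matched on brightness. With that correlation 0 of the 21 lists called in Huh1 passed by camera, against 3 of 13 in Hep3B; fry, which tests each list against no change, called 11 in Huh1. On data simulated with the spread of each line, 28.5% of the genes called in Huh1 by the fit over all arrays were false. In Hep3B the share was 4.92%. Fewer genes were changed there, 100 by 0.5 and 100 by 1 in each line, than were called on the real arrays. Such shares depend on how many genes change, so they are not the false shares of the real calls. The simulation also took each gene's observed spread in a line as its true spread. Noise in those estimates then counted as a real difference in spread between the lines.

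The responses of the 2 lines shared more genes than independent lists would. TPM4 (log2 fold change 1.64 in Hep3B, 1.42 in Huh1), EREG (1.56 and 1.07) and NTN4 (1.03 and 1.05) rose in both, and RAB8B (−1.60 and −1.64), BAG2 (−1.50 and −1.40), CA12 (−1.25 and −1.40) and ENTPD5 (−1.13 and −1.17) fell in both by similar amounts. In all, 586 genes were called in both lines with the same sign. Of these 221 rose, against 23.8 for independent lists (Fisher's exact test, odds ratio 25.4, 95% confidence interval 20.4 to 31.8, p = 4.39e-168), and 365 fell, against 36 (odds ratio 37.1, 30.7 to 45, p = 3.48e-306), although Fisher's test takes genes as independent. The balance was not stable, with 294 higher and 308 lower without Huh1 RDBP siRNA replicate 1, 293 and 352 after quantile normalization and 874 and 769 with array weights. Calls in both lines also rest on the same estimate of spread per gene, so a gene with a small spread passes more easily in both. The numbers for independent lists leave this out. A further 7 genes were called with opposite signs, for example NFE2L3, a transcription factor related to NRF2 (0.66 in Hep3B, −0.42 in Huh1), and S1PR3, a sphingosine phosphate receptor (0.55 and −0.35), named after their values were seen. Across genes the fold changes had a Pearson correlation of 0.50 and a Spearman correlation of 0.355, where genes are not independent replicates. Genes called in Hep3B had a median absolute log2 fold change of 0.37 there and of 0.14 in Huh1. Without Huh1 control siRNA replicate 2 the number shared was 361.

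**Figure D2:**
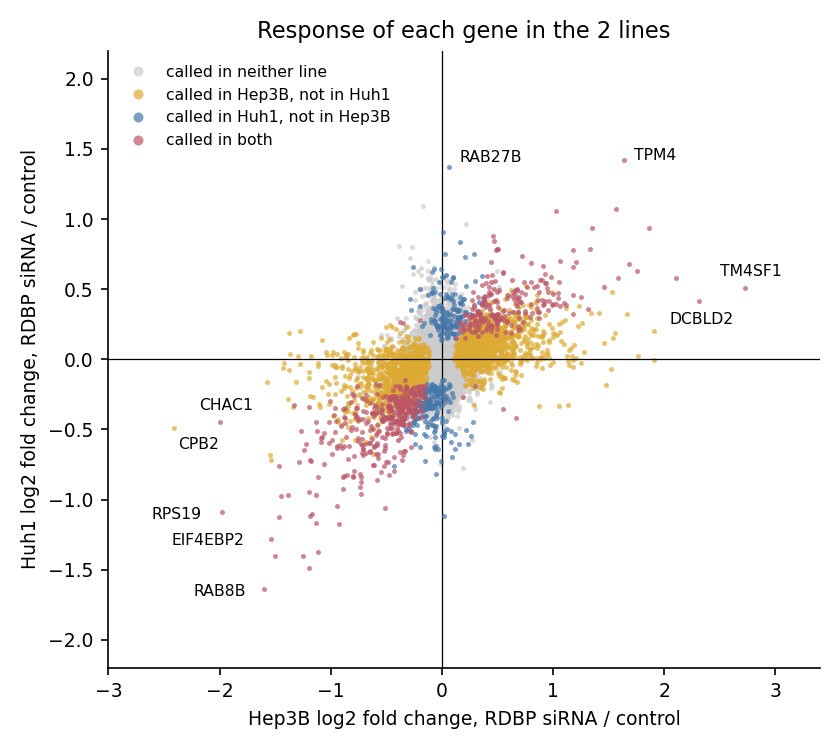
Log2 fold change (RDBP siRNA / control) of each of the 22465 genes in Hep3B (x axis) and Huh1 (y axis); colours mark genes called in both lines, in 1 line or in neither. Most of the genes called in both lie in the lower left or upper right part, and TM4SF1 and DCBLD2 lie far to the right with smaller values in Huh1.

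The interaction test asked which responses differed between the lines. The strongest increases of Hep3B were smaller in Huh1: the difference, Huh1 minus Hep3B, was −2.22 ± 0.17 (SE) for TM4SF1 (limma adjusted p = 0.000176), −1.92 ± 0.12 for B3GALT1, −1.90 ± 0.10 for DCBLD2, −1.74 ± 0.17 for CXCR4 and −1.71 ± 0.10 for HAS2. The decreases that differed most were those of CPB2 (difference 1.93 ± 0.24, adjusted p = 0.00238), LOXL4, an enzyme that crosslinks collagen (1.56 ± 0.10), CHAC1 (1.55 ± 0.09), the iron exporter SLC40A1 (1.48 ± 0.18) and the organic anion transporter SLCO4C1 (1.40 ± 0.26). The log2 fold changes of LOXL4 and SLC40A1 were −1.38 and −1.28 in Hep3B and 0.19 and 0.20 in Huh1, and the Huh1 values did not pass the test. SLCO4C1 lay at 2.57 to 2.75 in all Huh1 arrays, below the median of all probe sets, so a fall could not have shown there. B3GALT1 (3.06) and HAS2 (3.54) also lay below that median (3.69) in Huh1 control arrays, which leaves the exact size of their differences uncertain. In all 643 genes differed, 257 with a higher and 386 with a lower value in Huh1. Without Hep3B control siRNA replicate 1 SLCO4C1 was not called (adjusted p = 0.0507) and the count was 410; it was 409 without Hep3B RDBP siRNA replicate 2 and 399 without Huh1 control siRNA replicate 2.

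Hepatocyte secreted proteins stood out among the lists. Of 37 members 10 differed, each with the higher response value in Huh1, or 20 adjusted over the list alone (median difference 0.26, camera adjusted p = 1.16e-15; 0.0475 with an estimated correlation). The differences were 1.30 and 1.36 for ORM1 and ORM2, 0.88 for FGB and 0.98 for KNG1. The exact size for KNG1 is uncertain, since it was low in Hep3B with RDBP siRNA and only at 3.697 to 3.852 in Huh1 arrays. ATF4 and amino acid response genes differed in the same direction, 7 of 39 higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 5.39e-09; adjusted p = 0.185 with an estimated correlation), with CHAC1, DDIT4, an inhibitor of mTORC1 (0.57), and SHMT2 (0.53). Ribosomal protein genes did too, 5 of 46 higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 1.93e-08; adjusted p = 0.258 with an estimated correlation), with RPLP1 (0.89) and RPS19 (0.89). Complement and coagulation genes had 6 of 35 higher and 0 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00143; adjusted p = 0.185 with an estimated correlation), including C3 (0.96) and F7 (0.84), with the median at percentile 95.8 of random lists matched on brightness. Immediate early genes differed the other way, 8 of 37 lower in Huh1 and 0 higher (15 and 2 adjusted over the list alone; camera adjusted p = 7.48e-06; adjusted p = 0.285 with an estimated correlation), including SPRY4 (−0.83), EGR1 (−0.90) and KLF6 (−1.08).

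For MYC targets the difference had a median of −0.05, with 0 of 159 higher and 4 lower on either adjustment, among them ODC1 (−0.76 ± 0.07 SE, adjusted p = 0.000281). The list passed (camera adjusted p = 0.00388; adjusted p = 0.663 with an estimated correlation) but not without Huh1 control siRNA replicate 3 (0.185), without Huh1 RDBP siRNA replicate 1 (0.347) or after quantile normalization (0.191), and its median lay at percentile 16.8 of random lists matched on brightness. Replication genes had 6 of 66 lower and 0 higher (13 and 2 adjusted over the list alone; camera adjusted p = 0.000223; adjusted p = 0.554 with an estimated correlation) and did not pass without Huh1 RDBP siRNA replicate 1 (0.127), with the median at percentile 8.20 of matched random lists. RRM2, the small subunit of ribonucleotide reductase (−0.54), and the exonuclease EXO1 (−0.81) were among them. Of the 16 lists called in this test, 6 with a higher and 10 with a lower value in Huh1, 8 stayed called whichever array was left out. After quantile normalization 8 were higher and 6 lower, and after cyclic loess 6 and 6.

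**Figure D3:**
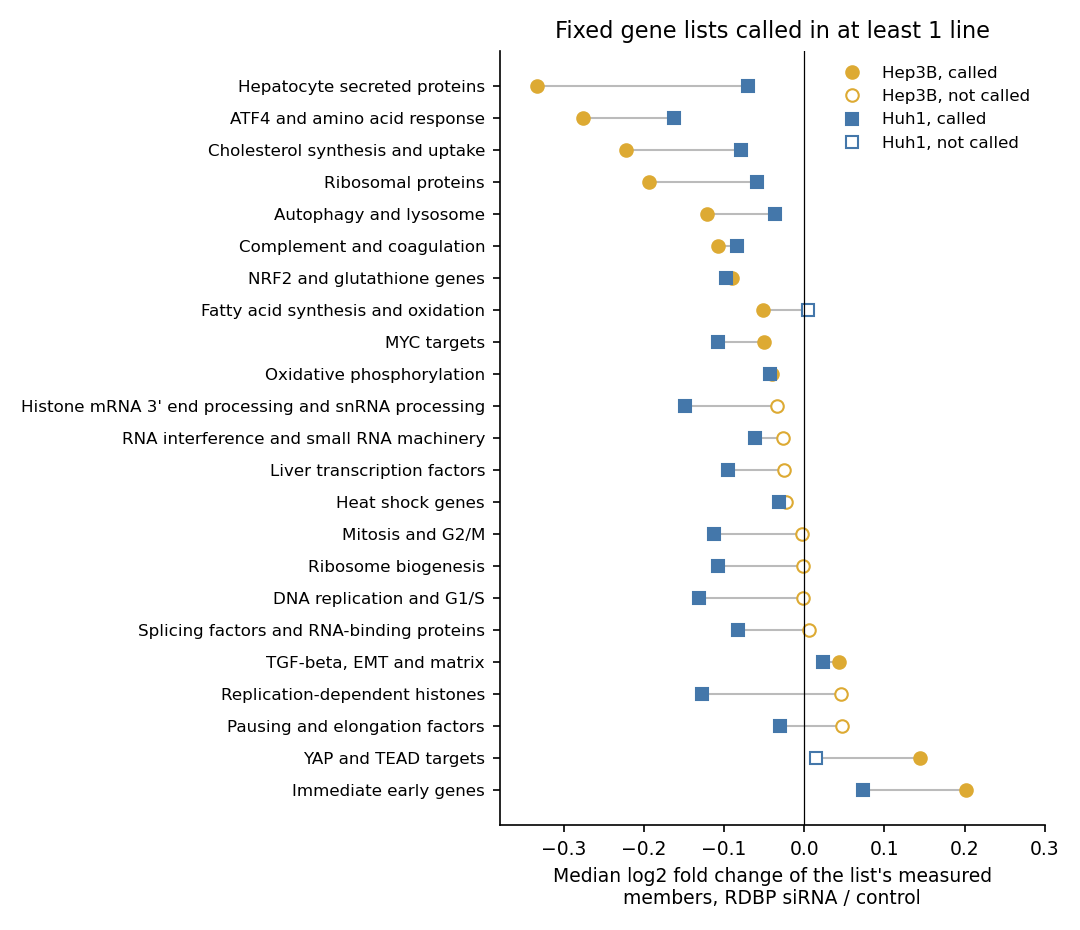
Median log2 fold change (x axis, RDBP siRNA / control) of the measured members of each fixed gene list (y axis) that was called in at least 1 line; circles are Hep3B and squares Huh1, filled where camera called the list. Hepatocyte secreted proteins have the lowest median in Hep3B, at −0.33, against −0.07 in Huh1.

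With control siRNA the lines differed widely, in genes of detoxification, liver metabolism and signaling. Higher in Huh1 were F2RL2, a thrombin receptor (238-fold, limma adjusted p = 2.24e-12), the aldo-keto reductases AKR1B10 (216-fold), AKR1C2 (158-fold) and AKR1C1 (137-fold), whose sequences are alike, and SPP1, which encodes osteopontin (129-fold). Higher in Hep3B were DKK1, a secreted WNT inhibitor (188-fold), GJA1, which encodes connexin 43 (41.0-fold), the sodium channel SCN9A (38.8-fold), DCDC2 (36.6-fold) and PROM1, which encodes the progenitor marker CD133 (28.5-fold). The folds of F2RL2, DKK1, GJA1, SCN9A and DCDC2 are lower bounds at most, since in the line with less of them their mean lay below the median of all probe sets. In all 7588 genes differed, 3679 higher in Huh1 and 3909 higher in Hep3B, and with array weights 11652, 6674 higher in Huh1 and 4978 higher in Hep3B. All 3 Huh1 control arrays lay beyond all 3 Hep3B control arrays for each of these 10 genes. MYC was 1.78-fold higher in Huh1 (log2 0.83 ± 0.05 SE, adjusted p = 4.51e-07), and NELFE was higher by 0.25 ± 0.06 on the log2 scale (adjusted p = 0.0049).

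By list, 24 of 28 NRF2 and glutathione genes were higher in Huh1 and 1 was lower, or 25 and 1 adjusted over the list alone (median log2 difference 1.87, camera adjusted p = 1.39e-17; 0.0161 with an estimated correlation), among them NQO1, a quinone reductase (47.5-fold), and GSTA1, a glutathione transferase (41.9-fold). Of 48 genes of hepatocyte metabolism and drug handling 22 were higher in Huh1 and 6 lower (24 and 6 adjusted over the list alone; camera adjusted p = 0.000238; 0.0161 with an estimated correlation), among them CPS1 of the urea cycle (123-fold) and HPD of tyrosine breakdown (25.3-fold). Lower in Huh1 were 16 of 30 NF-kB and cytokine genes, with 1 higher (16 and 3 adjusted over the list alone; camera adjusted p = 0.000238; adjusted p = 0.203 with an estimated correlation), such as the chemokine CXCL5 (12.2-fold), and 16 of 27 YAP and TEAD targets, with 7 higher (17 and 7 adjusted over the list alone; camera adjusted p = 0.00259; adjusted p = 0.318 with an estimated correlation), such as CCN2 (6.33-fold) and ANKRD1 (7.99-fold). MYC targets did not stand apart, with 64 of 159 higher and 40 lower (67 and 45 adjusted over the list alone; camera adjusted p = 0.272). The folds of CPS1, GSTA1 and CXCL5 are lower bounds at most for the same reason. Of 38 lists tested 19 differed, 11 toward Huh1 and 8 toward Hep3B, and 2 of the 19 did so with an estimated correlation.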

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

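The splits of the arrays, the fits without 1 array and the estimated correlation were fixed before the data were examined, whereas their use on the 3 patterns weighed below, and the tests of carried-over change, cyclic loess, matched brightness, mixed splits, knockdown size and starting level there, were chosen only after the result was seen.

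The response differed between the lines by the interaction test in 643 genes. Other splits of both lines reached that number in 4 of 100 cases with the real split included, and the highest other split called 1559. Many splits that mixed the arrays of both lines called 0 genes. With the real Hep3B groups kept, splits that mixed the Huh1 arrays called, for example, 781, 692 and 439. The number therefore follows the Hep3B response closely, and the share of splits says little about a difference between the siRNA responses. Between responses, Huh1 minus Hep3B, the log2 difference was 1.93 for CPB2, 1.56 for LOXL4, 1.55 for CHAC1, 1.48 for SLC40A1 and 1.40 for SLCO4C1. It was −2.22 for TM4SF1, −1.92 for B3GALT1, −1.90 for DCBLD2, −1.74 for CXCR4 and −1.71 for HAS2. The exact sizes for SLCO4C1, B3GALT1 and HAS2 are uncertain, since these lay below the median of all probe sets in Huh1 control arrays. With an estimated correlation 1 of the 16 lists called by the same test stayed called, hepatocyte secreted proteins. The median differences, each with its camera adjusted p at that correlation, were 0.262 (0.0475) for hepatocyte secreted proteins, 0.16 (0.185) for ATF4 and amino acid response, 0.121 (0.258) for ribosomal proteins, 0.107 (0.35) for fatty acid synthesis and oxidation, 0.0845 (0.47) for cholesterol synthesis and uptake and 0.0394 (0.185) for complement and coagulation. Downward they were −0.182 (0.285) for YAP and TEAD targets, −0.173 (0.663) for replication-dependent histones, −0.134 (0.593) for ribosome biogenesis, −0.131 (0.285) for immediate early genes, −0.11 (0.757) for mitosis, −0.1 (0.554) for pausing and elongation factors, −0.0935 (0.554) for the proteasome, −0.0636 (0.554) for DNA replication, −0.0597 (0.782) for splicing factors and −0.051 (0.663) for MYC targets. Proteasome, DNA replication, splicing, MYC target and complement medians lay at percentiles 9.20, 8.20, 20.9, 16.8 and 95.8 of random lists matched on brightness. The 16 lists called were reached by 11 of 100 splits, the real split included, and the highest other called 21, so that number of lists may come from how the arrays happen to be grouped. In data outside the genes tested, transcript clusters without a single gene name, 1193 were called in Hep3B and 226 in Huh1.

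Splits of 3 arrays against 3 are too few for a share under 0.05. In Hep3B 1 of 10 splits reached the 2925 genes (highest other 0), 1 of 10 the 138 genes changed by 2-fold (highest other 0) and 3 of 10 the 13 lists (highest other 16). In Huh1 2 of 10 reached the 918 genes (highest other 1029), 1 of 10 the 19 genes changed by 2-fold (highest other 1) and 1 of 10 the 21 lists (highest other 17). For the control arrays of the lines 1 of 10 reached 7588 (highest other 0). The Huh1 split that called 1029 genes set control 3 with RDBP 2 and 3 against control 1 and 2 with RDBP 1, which points to structure among the Huh1 arrays that the groups do not describe. The 586 genes shared by the lines were reached by 1 of 100 splits (highest other 165), but nearly all other splits called 0 genes in at least 1 line and so could share none, which leaves this comparison little force. The correlation of 0.50 was also reached by 1 of 100, but the highest other split gave 0.494, a gap smaller than the SD of 0.0203 over arrays left out, so the value itself does not separate the real groups from that split.

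Of 38 genes that changed in the same direction in both lines by at least 0.728 in each, the size of the NELFE fall in Hep3B, 31 fell and 7 rose (81.6% lower), among them RAB8B, BAG2, CA12 and ARMC1. A brightness trend between arrays is argued against, since 75% were still lower after cyclic loess (95% confidence interval 57.8 to 87.9%). An siRNA acting on transcripts other than NELFE would make falls carry over between lines better than rises. Genes that fell by 2-fold in Hep3B kept a median of 35.2% of their change in Huh1, against 23.9% for genes that rose. This difference of 11.3 percentage points did not pass the test (permutation p = 0.0581). The permutation also treats genes as independent, so the comparison does not decide whether the siRNA acted on other transcripts. Such an action and loss of NELFE cannot be told apart, since 1 RDBP siRNA condition was used per line. A second siRNA sequence or a rescue is what would separate them.

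The MYC target, DNA replication and mitosis lists were lower in Huh1. A brightness trend in the Huh1 arrays is argued against, because the highest of their percentiles among random lists matched on brightness was 0.01. Huh1 RDBP siRNA replicate 1 as the whole cause is argued against only at the preset correlation, where the highest adjusted p without that array was 0.00457. The medians shrank without it, from −0.108, −0.131 and −0.113 to −0.079, −0.084 and −0.051, and with an estimated correlation none of the lists was called even with all arrays (adjusted p = 0.191, 0.259 and 0.359). However, of the 9 splits that mix control and RDBP arrays of Huh1, 4 also called all 3 lists lower and 1 called all 3 higher. Each of the 4 had RDBP siRNA replicate 1 on the lower side. Each also kept most RDBP arrays on that side, so part of any siRNA effect remains in them. These 4 therefore cannot separate spread between Huh1 cultures from the siRNA. The split that called the lists higher had most RDBP arrays on the higher side, so spread unrelated to the siRNA may move these lists. An effect of NELFE loss stays open.

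Hepatocyte secreted proteins fell more in Hep3B than in Huh1. A weaker knockdown in Huh1 is argued against at the RNA level, since the upper 95% bound of the difference of NELFE responses was 0.0695. A difference of 0.574 would be needed if the list's log2 response scaled with that of NELFE. The arrays do not measure NELFE protein, so a weaker loss of protein in Huh1 stays open. A low starting level in Huh1 is argued against as well, as the members that fell in Hep3B started higher in Huh1 by a median of 0.196, and 0 of these 21 lay below the median of all probe sets in Huh1 control arrays. The culture medium cannot be told apart from the line, because 0 lines were grown in the medium of the other.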

How the results depend on the processing

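Cyclic loess, the fit without both Huh1 arrays numbered 1 and the added probe sets were chosen after seeing the data, and all other settings were fixed before.

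NELFE stayed lower and called under every setting run for it, from −0.787 to −0.687 in Hep3B and from −0.862 to −0.808 in Huh1. Of values for named genes 6268 kept their direction and side of the threshold, 506 lost the call, 6 gained it and 2 reversed; for lists these were 1148 kept, 183 lost and 3 reversed. The reversals were MYC in Hep3B, not called, at −0.031 without Hep3B control siRNA replicate 2 and −0.001 without Hep3B RDBP siRNA replicate 1 (range over arrays left out −0.031 to 0.062), and, without Huh1 RDBP siRNA replicate 1, splicing factors in Huh1 (adjusted p = 0.873; range 2.03e-05 to 0.873) and in the interaction (0.939; 0.000846 to 0.939) and autophagy in Huh1 (0.945; 0.00636 to 0.945).

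Array weights gave 4157 genes in Huh1 and 4317 in Hep3B, 2422 for the interaction, 11652 between control arrays, 1643 shared and a correlation of 0.41. With every transcript cluster tested on its own, 253 and 37 changed by 2-fold in Hep3B and Huh1, 12797 differed between control arrays and the correlation was 0.355. With dim genes left out the correlation was 0.566, with 8 lists called in Hep3B and 12 in Huh1. The Huh1 arrays alone called 159 genes, 62 higher and 97 lower. At an adjusted p under 0.01 there were 1806 genes in Hep3B, 357 in Huh1, 243 for the interaction and 251 shared, by construction fewer. The estimated correlation left 3 lists in Hep3B, 0 in Huh1 and 1 for the interaction, and fry 11 in Huh1 and 6 for the interaction. In Huh1, quantile normalization called 12 lists, cyclic loess 11 and the fit without both arrays numbered 1 called 13. Except where fewer arrays or a stricter threshold show it, the cause was not tested.

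Leaving out each array in turn gave 2217 to 3522 genes in Hep3B, 496 to 854 in Huh1, 399 to 707 for the interaction, 6551 to 8356 between control arrays and 361 to 602 shared. Genes changed by 2-fold numbered 130 to 155 and 18 to 23, lists 10 to 18 in Hep3B, 12 to 22 in Huh1 and 11 to 17 for the interaction, and the correlation was 0.456 to 0.526. Without Huh1 RDBP siRNA replicate 1 the Huh1 genes were 435 higher and 419 lower, against 368 and 550. Replicate numbers were treated as not pairing samples. With the number as a replicate block within each line, 3143, 961, 586 and 8096 genes were called in Hep3B, Huh1, the interaction and between control arrays. The lines then shared 638 genes. Correlations of deviations with the same number were −0.054, 0.190 and −0.056 in Hep3B and 0.462, −0.172 and 0.348 in Huh1, and not every sample correlated best with its own number. Arrays were compared within a line, so a component shared by number across the lines was not tested. Signal over background limits what dim genes can show, since the median gene lies at 4.83 and background medians reach 2.75.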

Other observations

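The transcript class tested below was fixed before it was tested as a set, but after the ribosomal protein and snoRNA host results were seen. Its members PABPC1 and NAP1L1 also belong to the MYC target list. The list of snoRNA host genes was fixed before the data were examined. The probe sets with resolved names that made it large enough to test were added after seeing the data.

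Host genes of small nucleolar RNAs, whose introns carry guides for ribosomal RNA modification, mostly have several symbols on this array. Of the 16 measured 3 carry a single symbol and the others enter with resolved names. In Hep3B 12 of 16 fell and 0 rose, or 14 and 0 adjusted over the list alone (median −0.41, camera adjusted p = 8.32e-13; adjusted p = 0.0744 with an estimated correlation). In Huh1 5 fell and 0 rose, or 14 and 0 adjusted over the list alone (median −0.28, camera adjusted p = 6.33e-13; adjusted p = 0.0849 with an estimated correlation). GAS5 had log2 fold changes of −0.605 and −0.468, SNHG8 −0.875 and −0.344, SNHG6 −0.515 and −0.392 and SNHG12 −0.361 and −0.375 in Hep3B and Huh1. Among the NELF partners NELFA (0.007 and −0.022) and NELFCD (−0.001 and −0.076) did not change detectably in either line, and NELFB rose by 0.30 in Hep3B (limma adjusted p = 0.0261) but not detectably in Huh1 (0.157, adjusted p = 0.379).

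Ribosomal protein and snoRNA host transcripts share a 5' terminal oligopyrimidine tract, a motif that couples translation and stability to growth signals, so 15 other transcripts of that class were tested as a hypothesis. Of 13 measured, 10 lay below 0 in Hep3B and 13 in Huh1 (EIF3F at −0.000229), with medians of −0.157 and −0.118. An exact sign-flip test of the mean, not the median, gave p = 0.00879 and 0.000244, and it treats genes as independent. EEF1B2 had −0.284 and −0.172, EIF4B −0.321 and −0.172 and PABPC1 −0.241 and −0.140, with 5 called lower in Hep3B and 0 in Huh1. These values go with a fall of the class in both lines, although with an estimated correlation camera gave p = 0.166 and 0.135. The sign-flip test compares with 0 and not with equally bright genes. In Huh1 the ribosomal protein list had a median of −0.0594, at percentile 11.8 of random lists matched on brightness. The arrays therefore do not settle whether the class fell.

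Of the unnamed clusters called, 490 were higher and 703 lower in Hep3B, 2.73% of 43747 against 9.93% of named clusters, and 94 higher and 132 lower in Huh1, 0.517% against 2.24%.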
